A study of Populus tremula x Populus tremuloides with 6 samples.

How the data were processed

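RNA-seq libraries were made from leaves of sunlight-exposed hybrid poplar, 3 WT and 3 MYB134 RNAi, grouped by the sample titles, which the genotype labels match. Per the labels' protocols, plants spent 1 month in a mist chamber and 2 months in a greenhouse before 2 weeks outdoors. RNA was extracted with a modified cetyl trimethyl ammonium bromide method for tissue rich in polyphenols, mRNA was purified with magnetic beads, and libraries were made with a NEBNext Ultra RNA kit and pooled in a set of 12, of which the 6 described here were given. The series' design text describes the plants as separate saplings. All 3 RNAi titles carry the same number, 24, which the labels do not explain, and whether they come from more than 1 transformation event is not stated.

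The authors deposited 1 file of raw read counts per sample, with no normalization. The tools HISAT2 2.1.0, Cufflinks, HTSeq 0.6.1, DESeq and R 3.4.0 are named, per the submitters' processing notes, without roles. The genome build, the annotation and the strand setting are not given in the sources used here. The locus numbers have the form that Cufflinks gives to assembled loci, and the files hold 37327 loci and 5 summary rows of the form that HTSeq writes. These summary rows were left out of library sizes and tests. As a share of all deposited counts, reads overlapping more than 1 locus made up between 9.72% and 12.8%, reads of low alignment quality between 5.10% and 6.17%, unaligned reads between 6.48% and 6.94%, reads aligned to several places between 2.00% and 2.69%, and reads in no locus between 1.48% and 1.85%. RNAi replicate 3 had the highest share aligned to several places and in no locus, and the lowest share overlapping more than 1 locus and of low alignment quality. Reads that overlap neighbouring loci, or that fit near-identical gene copies, were therefore set aside, and a locus with a close copy can be undercounted.

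The files do not pair locus numbers with gene names or coordinates, and no genome or annotation was used here. The 21 gene lists and 6 marker lists fixed before the data were examined, which covered the flavonoid and proanthocyanidin pathway, photosynthesis, stress, defence and other leaf cell types, could therefore not be matched to loci. None of them was tested, and neither was the MYB134 transcript. The fallback in the naming rule was used: the 2 loci with the largest change in a direction among those past the threshold, with groups that did not overlap and a mean of at least 1 CPM. Other loci that are named were chosen after their values were seen.

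Counts were analysed with edgeR 4.0.16 in R 4.3.3. Loci were kept by filterByExpr with its defaults, which left 24853, libraries were scaled by TMM, and genotype was tested with the quasi-likelihood F test (robust fit, no covariate) with Benjamini-Hochberg adjustment at 0.05. An approximate SE was computed as the absolute log2 fold change divided by the square root of F. CPM values were computed here from the deposited counts with TMM-scaled library sizes. Shares of counts were computed without scaling. The lowest level that a library could exclude, taken as 3 counts, was between 0.0314 CPM in RNAi replicate 3 and 0.125 CPM in WT replicate 2, and covers counting error only. The common dispersion was 0.1005, a biological coefficient of variation of 0.317. Libraries of a group were not alike within sampling noise: the chi-square per degree of freedom of their counts was between 11.2 and 362.

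The fit was tested on simulated data for the comparison of MYB134 RNAi with WT, with 24853 loci drawn from the real means, library sizes and dispersions and 200 changed loci. At a 2-fold change 13.4% of changed loci were recovered, at 4-fold 76.1% and at 16-fold 87.9%, with 8 false calls among 126. The real fit gave 13 calls, so the adjusted threshold was less strict in the simulation. Variation was also spread evenly over the 6 libraries, although RNAi replicate 3 stood apart. The recovered shares may therefore be too high for the real data.

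WT and RNAi libraries share the replicate numbers 1 to 3, which the labels do not tie to a batch or day. The deviations of same-numbered libraries from their group means correlated at -0.09, 0.36 and 0.17, so the numbers were not taken to pair the samples, and the block is given only as an alternative. Alternatives were other normalizations, filters, tests and thresholds, and leaving out each library. Sample quality weights (limma 3.58.1), thinning to equal depth and removal of the most abundant locus were added after seeing the data. DESeq2 1.42.0 was run with its defaults at an adjusted p of 0.05 and gave no adjusted p for 9371 loci. No-change values for a library left out of the calling were taken from 20 simulated data sets per case and from the 9 other splits of the remaining 5 libraries.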

Results

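Leaf RNA was sequenced from 3 wild-type (WT) and 3 MYB134 RNAi plants of the hybrid poplar Populus tremula x Populus tremuloides, all exposed to natural sunlight outdoors for 2 weeks after growth in a greenhouse. MYB134 is a transcription factor known as an activator of proanthocyanidin (condensed tannin) synthesis in poplar. The RNAi plants carried a hairpin built from a 169 bp fragment of its coding sequence, driven by a ubiquitin promoter. The comparison addressed which leaf transcripts differ in abundance between sun-exposed WT and MYB134 RNAi plants. Each library was deposited as raw read counts for 37327 assembled loci, named by number only. The tables do not pair these numbers with gene names, so transcripts are described here by locus, and the MYB134 transcript itself, and with it the extent of the knockdown, was not analysed here.

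Counts assigned to loci ranged from 24001320 in WT replicate 2 to 95496664 in RNAi replicate 3. In units of 1000000 counts, the mean was 28.6 ± 7.82 (SD, n = 3) in WT and 64.6 ± 26.9 (SD, n = 3) in MYB134 RNAi, and each RNAi library was deeper than each WT library. Counts were found at 32404 loci in at least 1 library, and 24853 loci passed the filter on low counts. The libraries detected between 27989 and 31075 loci. The most abundant locus over the 6 libraries, XLOC_037099, was singled out after its values were seen. It took 7.20%, 2.60% and 8.10% of the counts in the 3 WT libraries and 8.58%, 4.03% and 3.4% in the 3 RNAi libraries. In edgeR's quasi-likelihood test it did not differ between the groups (log2 fold change -0.21, Benjamini-Hochberg adjusted p = 0.93).

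A small set of loci was strongly reduced in MYB134 RNAi leaves, and edgeR called no locus higher with all 6 libraries. In edgeR's quasi-likelihood test 13 loci passed an adjusted p of 0.05, and all 13 were lower in MYB134 RNAi. Their median log2 fold change was -4.09, a 17.0-fold reduction, and the single loci were reduced between 5.17-fold and 42.3-fold. In 12 of the 13 loci the reduction was larger than 8-fold. At every one of the 13 loci the 3 RNAi libraries all lay below the 3 WT libraries, which follows largely from the call and adds no support. Over the 24853 tested loci, 13.6% had groups that did not overlap, 1685 of them lower and 1686 higher in RNAi. By chance 10% would be expected for 3 libraries against 3, both directions together.

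The reduced loci covered a wide range of abundance in WT leaves, from a mean of 4.06 to 272 CPM (counts scaled to a library of 1000000). A WT mean of at least 100 CPM was found at 5 of them, and 5 had a WT mean under 20 CPM. The level remaining in RNAi leaves was between 2.35% and 19.4% of the WT mean, with a median of 5.91%. The largest reduction was at XLOC_020968, which fell from 112 CPM ± 55.5 (SD, n = 3) in WT to 2.64 CPM ± 0.811 (SD, n = 3) in MYB134 RNAi. Its log2 fold change was -5.40, with an approximate SE of 0.45 and an adjusted p of 0.045 in edgeR's quasi-likelihood test. The next largest was at XLOC_026039, which fell from 28.3 CPM ± 9.94 (SD, n = 3) to 0.854 CPM ± 0.384 (SD, n = 3). Its log2 fold change was -5.09, with an approximate SE of 0.48 and the same rounded edgeR adjusted p of 0.045. Together the 13 loci took 0.1004% ± 0.031 (SD, n = 3) of all assigned counts in WT and 0.00624% ± 0.00115 (SD, n = 3) in MYB134 RNAi, a ratio of 16.1. An exact permutation test of these shares gave p = 0.1, the smallest value possible with 20 arrangements. The loci had been chosen for being lower in the same RNAi libraries, so this test adds no support.

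**Figure D1:**
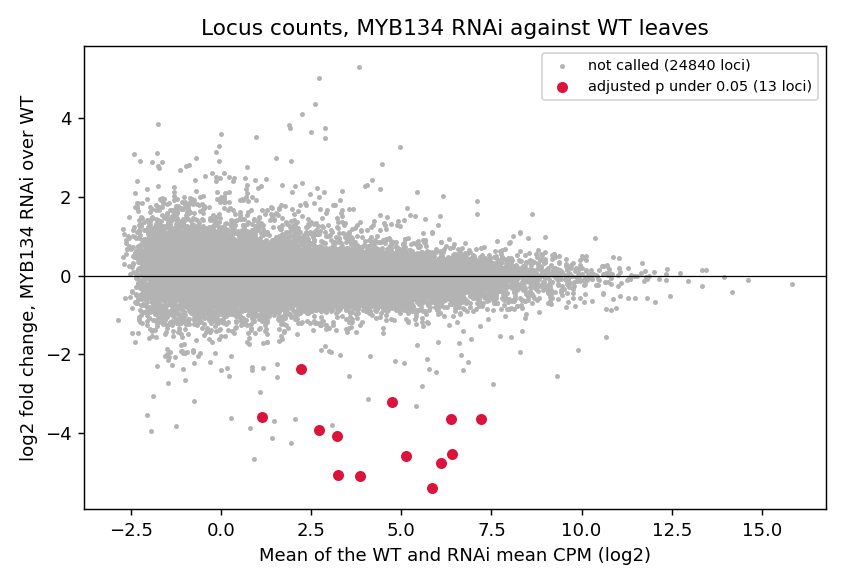
Each point is 1 of the 24853 tested loci, with the log2 of its mean CPM on the x axis and its log2 fold change of MYB134 RNAi over WT on the y axis. The 13 loci with an edgeR adjusted p under 0.05 are in red and all lie between log2 fold changes of -5.40 and -2.37.

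**Figure D2:**
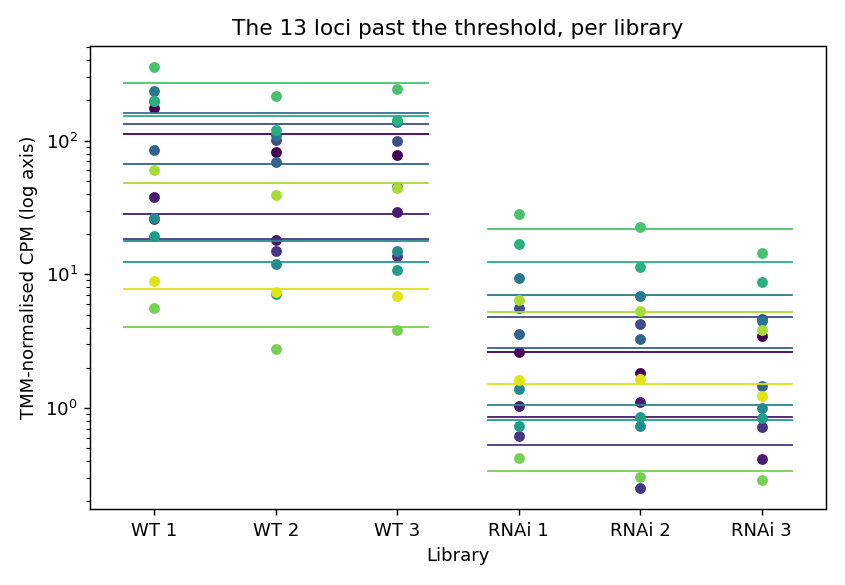
Each point is the TMM-normalised CPM of 1 of the 13 reduced loci in 1 library, on a log axis, with 1 colour per locus and a horizontal line at its mean over the 3 libraries of a group. For each locus the 3 RNAi libraries lie below the 3 WT libraries.

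The edgeR adjusted p-values of the 13 loci lay between 0.0449 and 0.0456, close to the threshold, and the next locus had 0.0613. Leaving out 1 library changed the number of called loci to 52 without RNAi replicate 3, to 2 without WT replicate 1 and to 0 without any one of the other 4 libraries, and all 13 loci stayed lower in RNAi in each of these 6 fits. The median log2 fold change of the 13 loci lay between -4.33 and -3.68 in these fits, against -4.09 with all libraries.

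In the other direction, no locus was called higher in MYB134 RNAi by edgeR's quasi-likelihood test. The smallest adjusted p among loci with a positive fold change was 0.203. At an unadjusted p under 0.05, 647 loci were higher and 462 were lower, together 1109, where 1243 of the tested loci would be expected by chance. This balance changed with the fit: limma-voom gave 507 higher and 586 lower, edgeR with upper-quartile factors 812 and 386, edgeR without RNAi replicate 3 gave 687 and 727, together 1414, and voom with sample quality weights 979 and 950, together 1929. DESeq2 called 13 loci higher, limma-voom called 0, and voom with sample quality weights called 2. The median half-width of the 95% interval of a log2 fold change was 0.57 before adjustment for the number of loci, and in simulated data 13.4% of the loci changed 2-fold were recovered, so most differences of that size were not detectable.

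The RNAi replicate 3 library stood apart from the other 5. The first principal component of log2 CPM held 61.9% of the variance and placed this library at 138, with the other 5 between -56.2 and -18.5. Its Pearson correlation with the other libraries, across loci, which are not independent replicates, lay between 0.878 and 0.916, while the lowest correlation among the other 5 was 0.965. In this library 159 loci were more than 4-fold above all other libraries and 660 were more than 4-fold below them. The corresponding numbers were 13 and 37 in WT replicate 2 and at most 1 and 0 in the remaining 4 libraries.

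**Figure D3:**
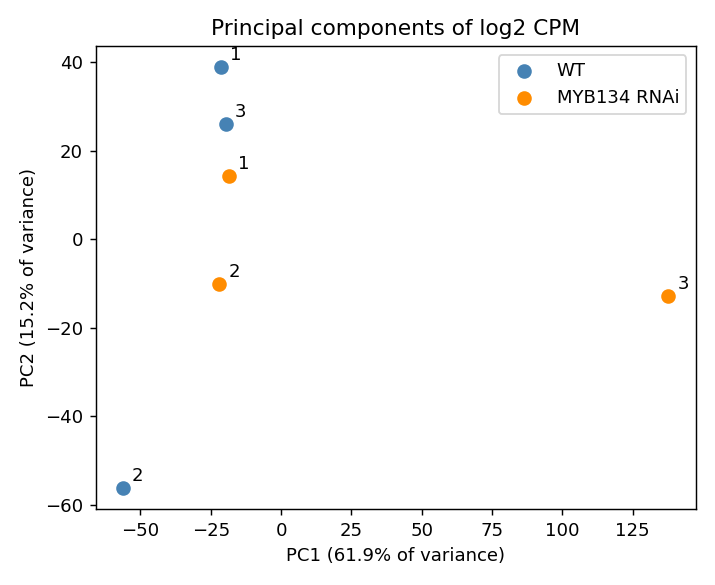
Each point is 1 library, numbered by replicate, on the first and second principal components of log2 CPM over the tested loci (no units). RNAi replicate 3 lies at 138 on the first component and the other 5 libraries lie at or below -18.5.

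Without RNAi replicate 3, more loci were called, again mostly lower in RNAi leaves. The edgeR quasi-likelihood test then called 49 loci lower and 3 higher at an adjusted p under 0.05. The median reduction of the 49 loci was 3.79-fold, and 23 of them were reduced more than 4-fold. They included 10 of the 13 loci called with all libraries. Their mean WT level was at least 1000 CPM at 3 loci and at least 100 CPM at 16 loci, and was under 10 CPM at 10 loci. The 49 loci together took 0.871% ± 0.165 (SD, n = 3) of the counts in WT and 0.275% ± 0.00199 (SD, n = 2) in RNAi replicates 1 and 2, a ratio of 3.17. In RNAi replicate 3, which had no part in calling them, they took 0.184%. There 45 of the 49 loci lay below all 3 WT libraries and 4 lay above all 3. The summed shares weigh the most abundant loci most. They were not tested, since the loci had been chosen for being lower in RNAi replicates 1 and 2 than in the same WT libraries.

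The 3 loci called higher without RNAi replicate 3 changed less than most of the lower ones, and those named here were chosen after their values were seen. XLOC_008794 had 8.28, 5.55 and 9.01 CPM in the WT libraries and 21.5 and 25.2 CPM in RNAi replicates 1 and 2 (log2 fold change 1.61, edgeR adjusted p = 0.0076). It had 57.7 CPM in RNAi replicate 3. XLOC_013112 had between 22.7 and 24.6 CPM in the WT libraries and 48.2 and 51.8 CPM in RNAi replicates 1 and 2 (log2 fold change 1.08, edgeR adjusted p = 0.0038). It had 34.8 CPM in RNAi replicate 3. The third locus had a log2 fold change of 0.95 and an edgeR adjusted p of 0.039, and its level in RNAi replicate 3, 7.47 CPM, lay within the WT range of 6.78 to 8.49 CPM. With all 6 libraries none of the 3 passed the edgeR test, with adjusted p-values between 0.393 and 0.832. DESeq2 called the 2 named loci higher with all 6 libraries, with adjusted p-values of 6.71e-05 for XLOC_008794 and 0.0071 for XLOC_013112.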

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

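Sample quality weights, thinning and removal of the most abundant locus were chosen after seeing the data. All 13 loci stayed lower in RNAi in every fit run, and their number was within 1.5 times of 13 with other size factors, with a filter at 1 CPM, after thinning (11) and without the most abundant locus. It moved to 24 with no filter on low counts, to 7 with limma-voom, to 82 with DESeq2 (69 lower, 13 higher) and to 51 with voom and quality weights (49 lower, 2 higher). The quality weight of RNAi replicate 3 was 0.120, so this library counted for little in that last fit. The number of called loci was 0 when edgeR tested against a 1.5-fold change and 0 at an adjusted p under 0.01. Leaving out 1 library gave between 0 and 52 calls, between 0 and 49 lower and between 0 and 3 higher: 52 without RNAi replicate 3, 2 without WT replicate 1, and 0 without any one of the other 4, where the smallest adjusted p of the 13 loci was between 0.106 and 0.349. The cause of these changes was not tested. The replicate block gave 15 lower calls, 9 of them among the 13. WT replicates 2 and 3 correlated best with the RNAi library of their own number (0.36 and 0.17), and WT replicate 1 did not (-0.09). Adjusted p rose above 0.05 for XLOC_020968 in 5 of the 6 fits without 1 library, and for XLOC_026039 with limma-voom (0.096), the block (0.151) and after thinning (0.080) and in 5 of the 6 fits without 1 library. Over these 6 fits the log2 fold change lay between -5.66 and -4.92 for XLOC_020968 and between -5.35 and -4.71 for XLOC_026039. Depth limits the weakest loci: the shallowest library cannot exclude levels under 0.125 CPM. The alternatives listed for the MYB134 transcript, the flavonoid list and the other gene lists were not run, because locus numbers were not matched to genes.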

Other observations

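The tests of explanations in this part, the fit with quality weights and the thinning were chosen after the results they bear on had been seen; DESeq2, the replicate block and the fits without 1 library were chosen before the data were examined. The lists of reduced loci from different fits overlapped in part. All 13 loci were also among the 69 that DESeq2 called lower and among the 49 called lower with quality weights. Of the 49 called lower without RNAi replicate 3, DESeq2 shared 43 and the quality-weighted fit 40, where independent lists of these sizes would share 0.136 and 0.0966 loci. The replicate block called 15 lower loci, of which 9 were among the 13 and 9 among the 49 called without RNAi replicate 3. These fits use the same libraries, so the overlap is not independent evidence. The quality-weighted fit gave RNAi replicate 3 a weight of 0.120, against 0.841 to 2.00 in the other libraries. It therefore came close to the fit without that library. One locus that did not reach the filter on low counts had 0 counts in each WT library and 11, 13 and 19 counts in the RNAi libraries, at least 6.35-fold higher than a floor of 3 counts over the WT group. It was not called by DESeq2 (adjusted p = 0.303), and 0 loci showed the opposite pattern with at least 10 counts in each WT library.

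The reduced loci moved with genotype, and 3 technical readings were set against that. The real split of the 6 libraries gave 13 calls and the highest other split gave 0; with 1 of 10 splits reaching the real value, the splits are too few for a share under 0.05, and at an unadjusted p under 0.05 a split of WT replicates 1 and 3 with RNAi replicate 3 gave 1377 loci, more than the 1109 of the real one. After thinning every library to the shallowest depth, 11 of the 13 loci were still called, so most calls did not need the extra depth. The median log2 fold change of the 13 loci was then -4.25. Thinning keeps the expected share of each locus in its library, so this value was largely fixed in advance. A difference in preparation that went with the deeper RNAi libraries stays open. Selection on the libraries used for calling stays open. Of the 49 loci called lower without RNAi replicate 3, 45 lay below the same 3 WT libraries there (91.8%, exact binomial 95% interval 80.4% to 97.7%) and 4 above all 3. The loci were read in 1 library and are not independent trials, so the interval is too narrow if they vary together. Over the 24852 loci of that fit, RNAi replicate 3 lay below all 3 WT libraries at 37.5% and above them at 37.1%. In 20 simulations with no locus changed the share below was 57.1% on average (highest 65.3%). These gave RNAi replicate 3 the spread of the other 5 libraries, although it stood apart, so they can set the share too low. Each of the 9 other splits of the 5 libraries was read at its own 49 leading lower loci. The highest share below the controls, 41 of 49 (83.7%), came with WT replicate 2 and RNAi replicates 1 and 2 as controls. An effect of the genotype, or of a transformation event that the RNAi plants have in common, stays open and untested.

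RNAi replicate 3 differed from the other libraries at many loci, and was low at most of the reduced ones. Its depth is argued against as the cause, because after thinning its highest correlation with another library was 0.917, still below the lowest among the other 5 (0.969). A WT leaf under an RNAi label is argued against: over the 49 loci called lower without it, the median log2 difference of this library from WT was -2.50 (bootstrap 95% interval over loci -2.99 to -2.25), against -0.50 to 0.29 in 10000 random lists matched on WT level. The interval treats loci read in 1 library as independent, so it is too narrow if they vary together. The random lists were not selected by a contrast. In 20 simulations with this library at WT levels and loci chosen by the contrast, the median lay between -0.13 and 0.11. These simulations gave it the spread of the other 5 libraries, although it stood apart. In the split with WT replicate 2 and RNAi replicates 1 and 2 as controls, 49 loci were taken by that split's own smallest p-values. They were not taken from the 49 called lower. They lay at -2.15 from those controls, so this library can lie that far below controls at loci not chosen by genotype. A WT leaf in which the 49 loci called lower were low for another reason is therefore not excluded. Added reads of another source are argued against for the 660 loci more than 4-fold below all other libraries, since added reads would lower all loci alike and no other library had more than 37 such loci. For the 159 loci above, which took 0.526% of its counts, the share of unaligned reads (6.52%) lay within the range of the other libraries. That share cannot decide the question for these loci, because reads that fail to align are not counted at any locus. This library was extreme in other read classes, with 2.69% aligned to several places (2.00% to 2.23% in the others), 1.85% in no locus (1.48% to 1.72%), 9.72% overlapping more than 1 locus (10.7% to 12.8%) and 5.10% of low alignment quality (5.38% to 6.17%), and added reads that align stay open. A different leaf age, position or stress of this plant was not tested.

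Among WT leaves, replicate 1 had the highest level at 13 of the 13 reduced loci, against 31.3% of all tested loci. When replicate 1 was left out of the calling, it lay above both other WT libraries at 36 of the 50 leading lower loci, with a median log2 difference of 0.58, above all of 10000 random lists matched on expression and on the size of the difference (percentile 100, with 95% of the lists between -0.13 and 0.33). The same reading put WT replicate 2 at -0.44 (below both others at 34 of 50 loci) and WT replicate 3 at -0.22, each also outside its random lists. In 20 simulations with loci varying independently, the left-out library lay between -0.49 and -0.17 for WT replicate 1. The range was -0.45 to 0.07 for WT replicate 2 and -0.49 to 0.03 for WT replicate 3. The value of replicate 1 lay outside the range of independent loci. That of replicate 3 lay within it, and that of replicate 2 lay just inside its lower end. A scaling error of this library is argued against, because in CPM without TMM the median difference was -0.056 over all tested loci and 0.52 over the 50. A candidate explanation is that the reduced loci share control that also varies between WT plants; this rests on 1 library, and a difference in the leaf sampled, which was not tested, stays open.

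If locus numbers followed genome order, reduced loci in tandem copies could carry consecutive numbers. Among the 100 lower loci with the smallest p, 1 consecutive pair was found as a test of whether lowered loci sit next to each other, against a mean of 0.281 in random lists matched on expression (permutation p = 0.246, 10000 lists), which leaves the hypothesis undecided.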
